A study of Arabidopsis thaliana with 4 samples.

How the data were processed

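Whole seedlings of Arabidopsis thaliana were compared after 16 h in a dilute liquid Murashige and Skoog medium with sucrose, either with aluminium at 50 µM or mock-treated. Per the labels, total RNA came from 100 pooled seedlings for each of 4 Affymetrix ATH1 arrays, 2 with aluminium and 2 controls, and complementary DNA was primed with poly dT before in vitro transcription with biotin. The labels state 2 biological replicates per treatment. The deposited values are one intensity per probe set and array, on a linear scale. The submitters' processing notes name GCOS and RMA, and the role of each is not given in the sources used here. In the deposited values, the mean without the lowest and highest 2% of probe sets was 500.0 on each array, and the sorted values differed between arrays, so the arrays were globally scaled and not quantile-normalized.

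Values were put on the scale log2(intensity + 16), so that fold changes of dim probe sets are understated. Of 22810 probe sets, the 64 control probe sets of the manufacturer were left out of the test and used to describe the arrays, which left 22746. No dim probe set was left out. A probe set was called above background when it exceeded the 95th percentile of 27 probe sets for bacterial genes on the same array. That level was 422 to 586, above the median plant probe set (327 to 351), while the median of the bacterial probe sets was 73.5 to 139. It is thus a strict cut and not a floor. The probe table used here paired 13513 probe sets with 1 gene and 503 with several, and 8730 had no gene name. Of the probe sets with 1 gene, 13436 were matched by Entrez identifier to a reference table of assembly TAIR10.1, which was used only for names. They covered 13355 genes, and 147 genes had several probe sets, of which the one with the highest mean was used for gene lists.

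Aluminium was compared with control by limma 3.58.1 in R 4.3.3, with a linear model of group and moderated two-sided tests. Benjamini-Hochberg adjustment ran over all 22746 probe sets, with a threshold of 0.05 on the adjusted p. A fold rule without a test counted probe sets whose group means were at least 2-fold apart and whose aluminium arrays lay both above or both below the control arrays. Gene lists were tested with camera of limma at a preset correlation of 0.01, on one probe set per gene and adjusted over the lists tested. For single genes, the adjusted p was also computed over the list alone. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

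The tests, the thresholds, the 24 gene lists with 407 members and the rule for naming genes were set before the data were examined. The lists covered aluminium resistance, the tricarboxylic acid cycle with malate and citrate metabolism, glutathione transferases, antioxidant enzymes, cell wall remodelling, auxin, ethylene, jasmonate, salicylate and defence, abscisic acid and dehydration, phosphate starvation, iron deficiency, photosynthesis, root markers, heat shock proteins, low oxygen, DNA damage, the cell cycle, glucosinolates, phenylpropanoids and flavonoids, aquaporins, carbon starvation, the circadian clock and reference genes. Lists with at least 2 measured members were tested, which were 16. The naming rule took the 12 genes with the largest difference in each direction among those past the threshold. Where fewer passed, the places went to the genes with the smallest limma p among those whose groups did not overlap. It also took all measured members of the aluminium resistance list and, in each other list without a member past the threshold, the 2 members with the largest difference. PRK was named in addition, after its value was seen, because the photosynthesis list had 3 measured members. A further 19 gene families were taken by gene symbol and genome after the data had been seen, and were tested and adjusted among themselves.

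Alternatives were the replicate number as a block, quantile normalization, median centring, leaving out the dimmest 25% or 50% of probe sets, pseudocounts of 1 and 64, a spread that follows the mean with or without robust estimation, a threshold of 0.1, one probe set per gene, and leaving out each array. For lists, the correlation estimated per list, fry and camera on ranks were tried. An estimated correlation and fry take the spread from only 4 arrays and have little power. A call lost with them is thus undecided and not refuted. Array weights, the arrays of each replicate number alone and the counts at an unadjusted p were added after the data had been seen. Medians of gene groups were also set against 10000 random lists of genes matched on mean expression in 20 bins. The steps were tested on simulated data with 22746 genes. With the spread of these arrays (prior SD 0.81 on the log2 scale), limma recovered 0 of 50 changed genes at each of 4-fold, 16-fold, 64-fold and 256-fold, with 0 false calls. With a spread of 0.20, it recovered 45 of 50 at 4-fold, 49 of 50 at 16-fold and 50 of 50 at 64-fold and at 256-fold, with 8 false calls.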

Results

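Transcript levels were measured in whole seedlings of Arabidopsis thaliana kept for 16 h in liquid medium with 50 µM aluminium or mock-treated. Aluminium ions are toxic to roots in acid soil, where they stop root growth. Each of the 4 arrays carried RNA from 100 pooled seedlings, with 2 arrays per treatment, and this number limits the precision. Of the 22746 plant probe sets, 35.1% lay above the background of bacterial control probe sets on aluminium replicate 1 and 42.0% on aluminium replicate 2. The share was 45.3% on control replicate 1 and 39.8% on control replicate 2.

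The arrays differed in their own controls. The geometric mean intensity of the 18 hybridization controls, bacterial and phage sequences added to the hybridization mix, was 131442 on aluminium replicate 1 and 51057 on control replicate 1. It was 11226 on aluminium replicate 2 and 6339 on control replicate 2. The 25S ribosomal RNA probe set read 3511 on aluminium replicate 1, 1362 on control replicate 1, 533 on aluminium replicate 2 and 416 on control replicate 2. The ratio of the 3′ to the 5′ probe set of GAPDH, which is larger when transcripts are shortened, was 3.52 on aluminium replicate 1 and between 1.44 and 1.71 on the other arrays. For actin it was 6.01 against 1.94 to 3.07, and for ubiquitin 4.29 against 2.21 to 3.29.

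**Figure D1:**
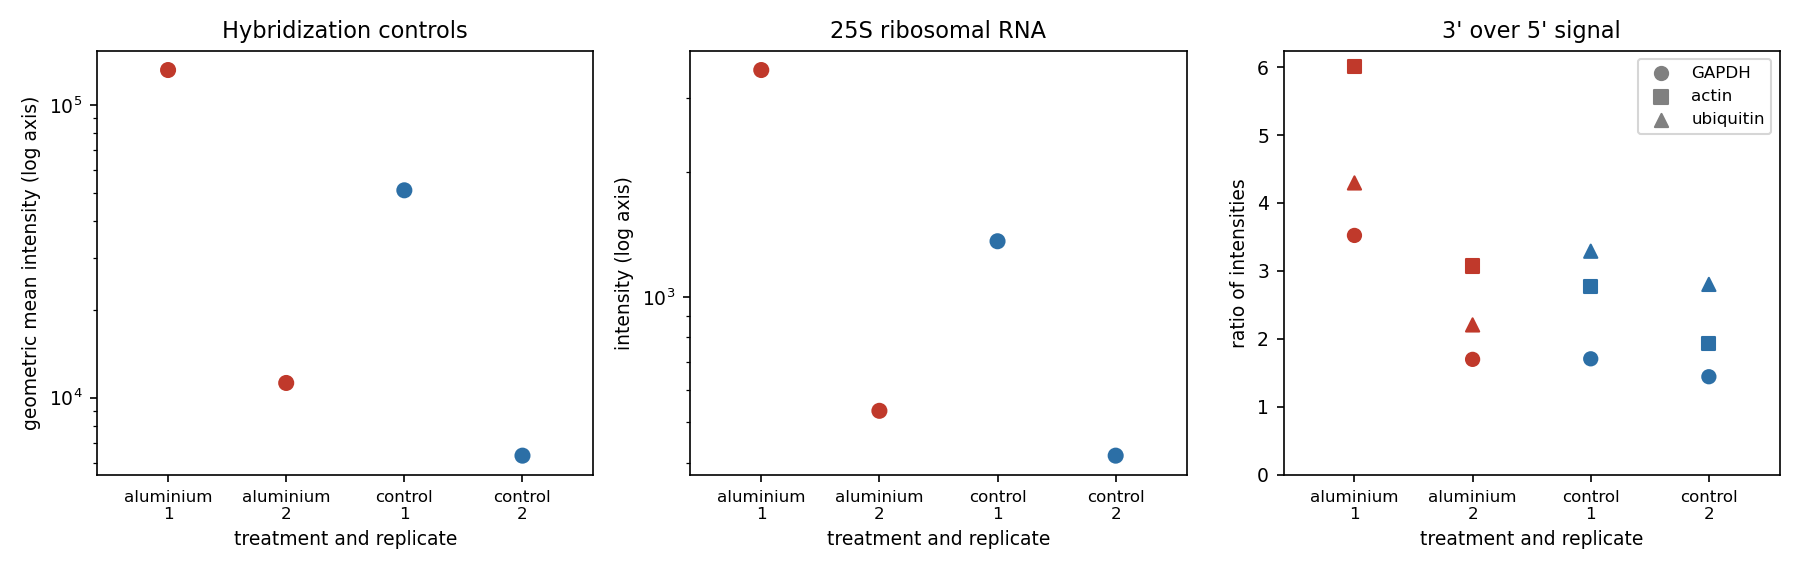
Controls of the 4 arrays: intensity of the hybridization controls and of 25S ribosomal RNA (log axes), and the 3′ to 5′ ratio of the intensities of GAPDH, actin and ubiquitin. Aluminium replicate 1 had the highest value in each panel, with hybridization controls at 131442 and an actin ratio of 6.01.

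The comparison of aluminium with control asked which genes respond to the metal in the whole seedling. The 3 measured genes of the photosynthesis list, of 19, were lower with aluminium as a group by camera at a preset correlation. That call was lost with an estimated correlation (adjusted p = 0.927 with an estimated correlation), and without aluminium replicate 1 or control replicate 1. With only 4 arrays, the loss with an estimated correlation leaves the call undecided. The probe table used here left 8730 probe sets without a gene name. Of 20 genes listed for aluminium resistance, it paired 2 with a probe set, a citrate exporter and an F-box protein. Both were higher on both aluminium arrays than on both controls, and neither passed limma. Groups did not overlap, in either direction, in 32.7% of all plant probe sets, where chance gives 33.3%. No single gene passed the test over all genes, and the other lists tested as groups did not pass with all 4 arrays.

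The photosynthesis list was the 1 of 16 tested lists past the threshold of camera, with a median of −1.91 on the log2 scale over 3 of its 19 members (adjusted p = 0.0124). The call was lost with an adjusted p = 0.927 with an estimated correlation, with fry (0.795) and with camera on ranks (0.0782). An estimated correlation and fry have little power with 4 arrays, so their result leaves the call undecided. It was also lost without aluminium replicate 1, where the median was −1.28 (adjusted p = 0.0904), and without control replicate 1, where it was −1.71 (adjusted p = 0.0978). The median was −2.34 between the arrays of replicate 1 and −0.93 between those of replicate 2. RCA encodes Rubisco activase, which keeps Rubisco in its active state, and its log2 intensity was 11.52 ± 0.32 (SD, n = 2) with aluminium and 13.43 ± 0.29 (SD, n = 2) in controls. The difference for RCA was −1.91, with a 95% interval from −3.59 to −0.23. LHCB4.1 encodes a light-harvesting protein of photosystem II and had 7.75 ± 2.34 with aluminium against 10.68 ± 0.49 in controls (SD, n = 2 each). The difference for LHCB4.1 was −2.93, with an interval from −5.86 to −0.01, and the gene read 52.3 on aluminium replicate 1 and 662 on aluminium replicate 2. PRK, the phosphoribulokinase of the Calvin cycle, differed by −1.49 with a standard error of 0.75. Over all genes 0 of these 3 genes passed limma (adjusted p = 0.966 each), and adjusted over the list alone 0 passed as well, with a smallest adjusted p of 0.0743.

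In the aluminium resistance list, 2 of 20 members were paired with a probe set in the table used here, and the others were not analysed here. MATE (AT1G51340) exports citrate, which binds aluminium outside the root. Its log2 intensity was 10.52 ± 0.16 with aluminium and 9.75 ± 0.14 in controls (SD, n = 2 each), a difference of 0.76 with a 95% interval from −0.88 to 2.40. RAE1 (AT5G01720) encodes an F-box protein that marks the transcription factor STOP1 for degradation. It had 9.86 ± 0.46 with aluminium and 8.51 ± 1.14 in controls (SD, n = 2 each), a difference of 1.35 with an interval from −0.70 to 3.40. The RAE1 difference was 0.54 without control replicate 1 and 2.15 without control replicate 2. Both genes were higher on each aluminium array than on either control. Groups without overlap, in either direction, made up 32.7% of all plant probe sets, where chance gives 33.3%. Neither gene passed limma over all genes (adjusted p = 0.966) or adjusted over the list alone, where the smallest was 0.296. The list had a median of 1.06 and did not pass camera (adjusted p = 0.719, and adjusted p = 0.927 with an estimated correlation). The median was 1.73 between the arrays of replicate 1 and 0.39 between those of replicate 2.

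Over all 22746 plant probe sets, limma found 0 past the threshold, with a smallest adjusted p of 0.966. In data simulated with the spread of these arrays, 50 genes were changed at each fold change tried. The same test recovered 0 of them, even at the largest. A count of 0 could thus be had where few genes changed, and does not show that genes were unchanged. A change in a large share of the genes was not simulated. At an unadjusted p under 0.05 there were 1084 probe sets, 536 higher and 548 lower with aluminium, where 1137 were due by chance. That number was 616 without control replicate 1 and 2532 without aluminium replicate 2. The typical 95% interval reached 1.98 to each side on the log2 scale, or 3.94-fold. A spread that follows the mean also gave 0, with a smallest adjusted p of 0.300, and 0.0954 with robust estimation in addition. The groups did not overlap in 7440 probe sets (32.7%), where chance gives 33.3%. Of these, 2197 were at least 2-fold higher with aluminium and 2258 at least 2-fold lower, 4455 in all. The same rule counted 5110 between the replicate 1 and the replicate 2 arrays, and 4059 for the remaining split of the 4 arrays into 2 and 2. With 1 array left out fewer comparisons can overlap, so counts made that way cannot be set beside 4455.

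The arrays of one treatment were about as alike as arrays of different treatments. Pearson's r across probe sets, which are not independent replicates, was 0.581 between the aluminium arrays and 0.674 between the controls. Across treatments it ranged from 0.528, for both replicate 1 arrays, to 0.770, for both replicate 2 arrays. The differences between aluminium and control in replicate 1 and in replicate 2 had an r of 0.0318 across probe sets and the same sign in 51.6%. With the controls exchanged, so that each aluminium array met the control of the other number, r was −0.0567 and the sign was shared in 48.2%. In the brightest 25% of probe sets r was 0.215 with 55.1% of signs shared, and 0.0260 with 48.7% for the exchanged controls.

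**Figure D2:**
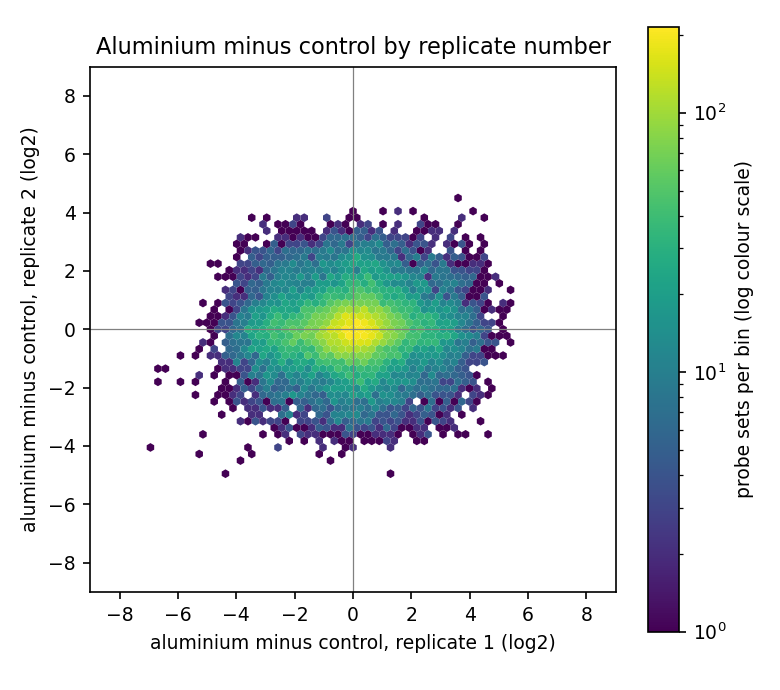
Log2 difference between aluminium and control in replicate 1 (horizontal) and in replicate 2 (vertical) for the plant probe sets, with colour for the number of probe sets per bin. The differences had r = 0.0318 across all probe sets and 0.215 in the brightest 25%, against −0.0567 and 0.0260 with the controls exchanged.

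Among the genes with non-overlapping groups, those with the smallest p are given as values, since none passed limma (adjusted p = 0.966 each). Of the 12 higher with aluminium, AT5G54300 differed by 4.14 on the log2 scale (standard error 0.68), with intensities of 907 and 899.9 against 27.8 and 46.4. AT1G59960, an aldo-keto reductase, differed by 4.03, and AT3G05500, a lipid droplet-associated protein, by 4.03. AT3G56120, a tRNA methyltransferase, differed by 3.79 and read 650 and 631 with aluminium against 31.7 and 31.4. The others were AT5G51260 (3.74), AT5G11000 (3.54), AT2G03380 (3.48), AT5G22555 (3.46), AT2G22590 (3.40), AT2G38800 (3.31), AT1G47920 (3.24) and AT1G05340 (3.15). In all 12 both control values lay under the background level of their array, and in 10 both aluminium values lay above it.

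Of the 12 genes lower with aluminium, rps19, which encodes a plastid ribosomal protein, differed by −5.51 (standard error 0.92) and read 43.6 and 81.8 against 7148 and 1672. GPDHC1, a cytosolic glycerol-3-phosphate dehydrogenase, differed by −3.57. AT1G12010, an ACC oxidase that makes ethylene, differed by −3.50. AT2G45180, a lipid-transfer-type protein, differed by −3.25, with 1324 and 1958 against 15556 and 15267, and was the 1 gene of the 12 with aluminium values above background. QQT2, known from embryo development, differed by −3.22. The others were AT3G09490 (−3.31), AT5G10710 (−3.28), AT1G75870 (−3.23), AT4G07510 (−3.09), AT5G06020 (−3.06), AT1G41860 (−3.02) and AT1G32690 (−2.97). In 8 of the 12, both control values lay above the background level.

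**Figure D3:**
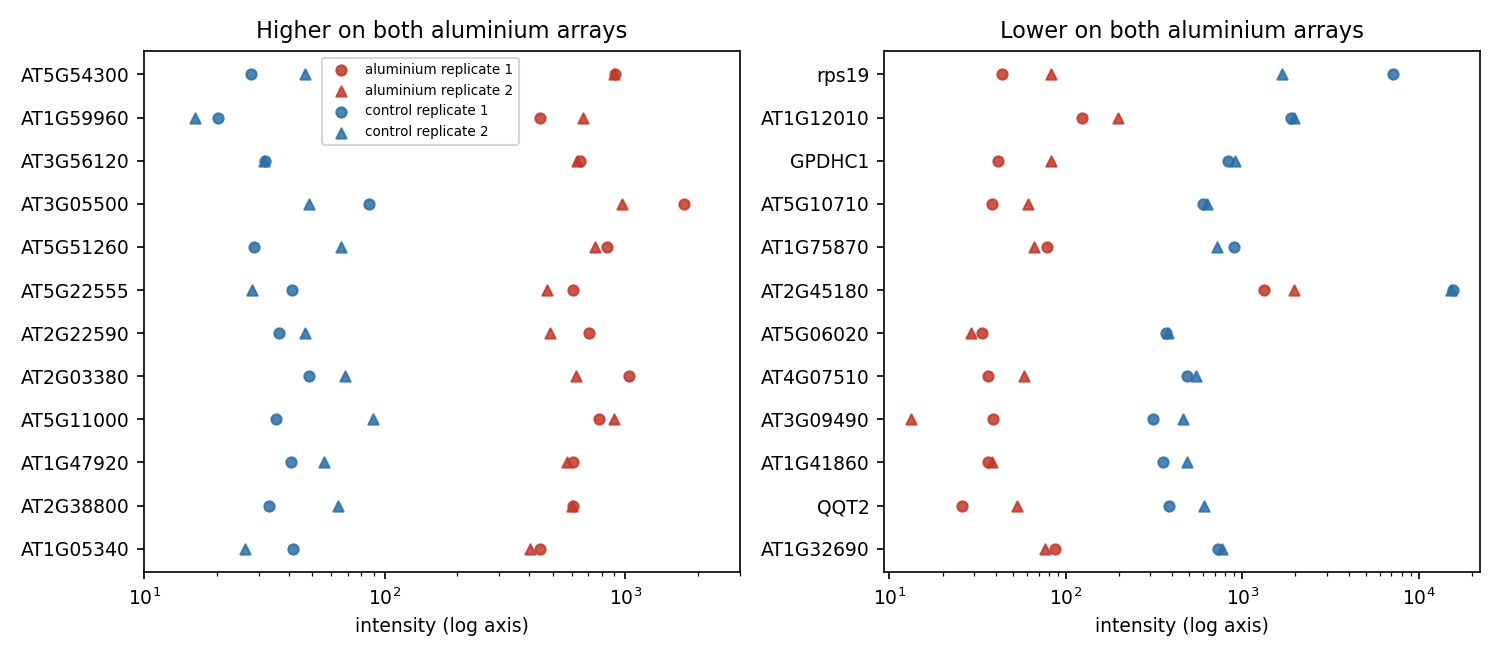
Intensity on each of the 4 arrays (log axis) of the 12 genes with the smallest p in each direction among those whose groups did not overlap. None passed limma (adjusted p = 0.966), and rps19 read 43.6 and 81.8 with aluminium against 7148 and 1672 in controls.

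The other 15 lists did not pass camera, with adjusted p from 0.719 to 0.960. In metabolism, the tricarboxylic acid cycle list, which feeds the malate and citrate that roots release, had a median of 0.09 over 11 of 33 members (adjusted p = 0.865). SCL-alpha2 (AT5G23250), a succinyl-CoA ligase subunit, differed by 1.49 with a standard error of 1.15. It read 657 and 767 with aluminium against 68.7 and 767 in controls. cICDH, the cytosolic isocitrate dehydrogenase, differed by 0.82 with a standard error of 0.68. Glutathione transferases, which detoxify reactive compounds, had a median of 0.26 over 8 of 33 members, with 5 higher and 3 lower, and GSTU22 (0.94) and GSTU28 (0.90) differed by the most. The carbon starvation list had a median of −0.20 over 3 of 7 members, with MCCA at −0.75 and ETFQO at −0.20. Glucosinolate biosynthesis had a median of 0.27 over 2 of 18 members, BCAT4 (0.36) and UGT74B1 (0.18). Phenylpropanoids and flavonoids had a median of −0.85 over 3 of 22 members. There, CCR2 of lignin synthesis stood at −1.82 with a standard error of 1.74, and UF3GT, an anthocyanin glycosyltransferase, at 1.10 with 0.71.

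In growth and the wall, cell wall remodelling had a median of −0.36 over 6 of 23 members, with XTH19 at 1.44 and EXPA4, an expansin, at −0.81. The cell cycle list had a median of −0.37 over 2 of 19 members, the Aurora kinases AUR2 (−0.88) and AUR1 (0.13). Auxin response had a median of −0.08 over 2 of 9 members, GH3.3 (−0.41) and IAA29 (0.26). Root markers had a median of −0.45 over 3 of 19 members, with PYK10, a root beta-glucosidase, at −0.65 and EXPA7 of root hairs at −0.45. Without aluminium replicate 1, PYK10 stood at −0.00022.

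In stress, heat shock proteins had a median of 0.26 over 4 of 15 members, with ATHSP22.0 at 0.93 and HSP17.6C (AT1G53540) at 0.68. Without control replicate 2 that list passed camera with a median of 2.10 (adjusted p = 0.0429). The call was lost there with an adjusted p = 0.867 with an estimated correlation, fry (0.503) and ranks (0.0606), and the median was 2.03 between the arrays of replicate 1 and −1.56 between those of replicate 2. In the low oxygen list, 3 of 16 members gave a median of −0.34, but a mean of 0.38 and an upward direction of the test. Its member HRA1 (AT3G10040), a repressor in the hypoxia response, differed by 2.36 with a 95% interval from 0.53 to 4.19, and LDH1 (AT4G17260) by −0.87. HRA1 read 549 and 251 with aluminium and 49.0 and 71.9 in controls, each under the background level of its array, and did not pass over all genes (adjusted p = 0.966) or adjusted over the list alone (0.0590). The abscisic acid list had a median of 0.42 over 3 of 14 members, with a mean of −0.08 and a downward test, from COR15B (−1.26), COR15A (0.60) and a further member. Iron deficiency had a median of 0.32 over 3 of 20 members, with a mean of −0.01 and a downward test (adjusted p = 0.960). There, BHLH101 stood at −0.71 and F6'H1 (AT3G13610) of coumarin synthesis at 0.36. The reference genes had a median of 0.24 over 3 of 11 members, with SAND (AT2G28390) at 2.03, where control replicate 2 read 68.5 and control replicate 1 read 1041, and PEX4 at −0.28. Each list without its own value here had an adjusted p of 0.865, and an adjusted p = 0.927 with an estimated correlation, or 0.964 for iron deficiency.

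A single member was measured in 4 lists, which were not tested. WRKY53 of the salicylate list differed by 1.70 (standard error 0.70), with 336 and 199 with aluminium against 58.1 and 81.2, all under the background level of their array. PDF1.2 of the jasmonate list differed by −1.26, and by −0.096 without control replicate 1. GR1 of the antioxidant enzymes differed by 0.58 and GI of the circadian clock by 0.27. No member of the aquaporin, DNA damage, ethylene and phosphate starvation lists had a probe set in the table used here, 0 of 18, 0 of 12, 0 of 8 and 0 of 14. Over all genes 0 of the 65 measured members passed limma, and 0 did adjusted over the list alone, while 33 were higher and 32 lower with aluminium. Of the 36 list members named under the rule, 14 lay under the background level on all 4 arrays, and the difference of 28 changed by a factor of more than 1.5 when 1 array was left out.

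**Figure D4:**
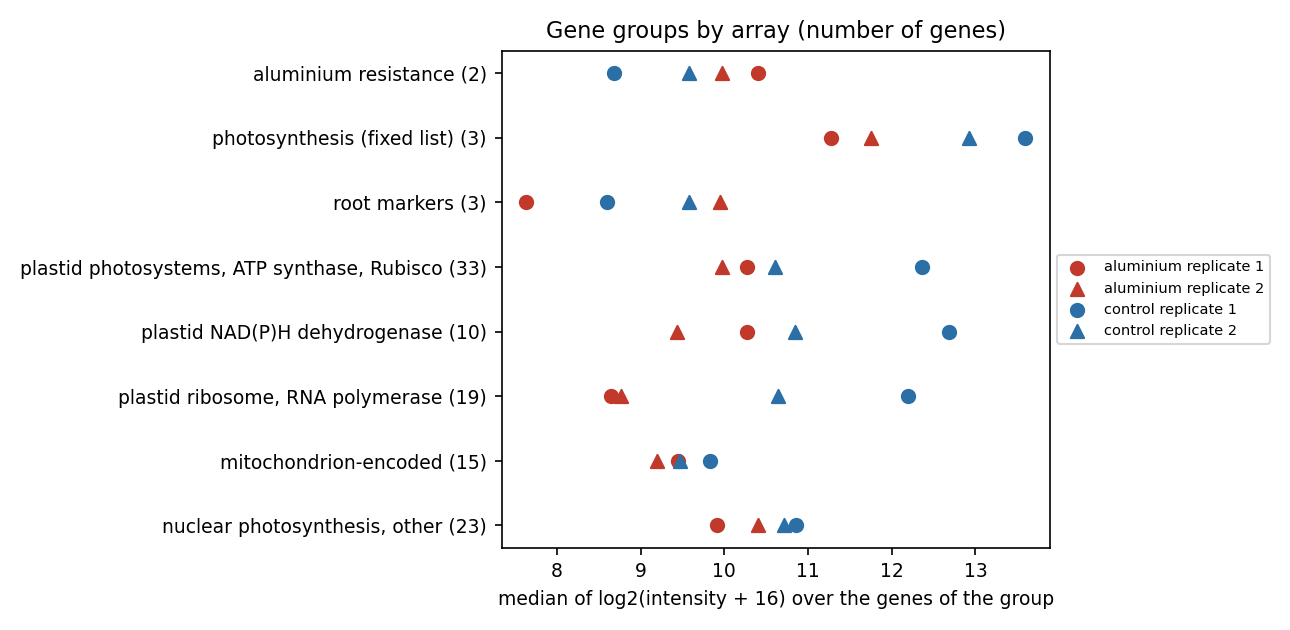
Median log2(intensity + 16) on each of the 4 arrays over the genes of 3 fixed lists and 5 families chosen after the data were seen, with the number of genes in brackets. The median difference between aluminium and control was −1.91 for the photosynthesis list and 1.06 for the aluminium resistance list.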

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

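Apart from the adjusted limma test and the fold rule for aluminium against control, the tests in this part were chosen late. They were set after the array controls and the likeness of the arrays had been seen. Both flagged results come from probe sets outside the comparison of genes, which read higher on aluminium replicate 1 than on either control array. The hybridization controls, added to every array, were 2.57 times as bright there as on control replicate 1, the higher control array. The probe set for 25S ribosomal RNA, which has no poly(A) tail, was 2.58 times as bright.

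Arrays of one treatment were no more alike than arrays of different treatments, with a mean r of 0.628 within and 0.632 between treatments. A weak plant signal on some arrays, whose scaling to a common mean would brighten the added controls, is consistent with this, since aluminium replicate 1 had both the brightest hybridization controls and the lowest mean r with the others (0.559), with control replicate 1 next (51057 and 0.622). That order rests on 4 arrays, and aluminium replicate 2 exceeded control replicate 2 in both measures (r of 0.672 and 0.670). RNA degradation stays open, since aluminium replicate 1 had the highest mean 3′ to 5′ ratio (2.17 on the log2 scale), but the arrays did not rank alike for all 3 control genes. An exchange of labels between an aluminium and a control array stays open too, since the mean r within groups after it was 0.649 or, for arrays of the same number, 0.616, against 0.628 as labelled, gaps too small to decide.

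Of the other splits of the same arrays, that by replicate number gave larger counts than the treatment, and the crossed split smaller ones. At an unadjusted p under 0.05, aluminium against control gave 1084 probe sets, replicate 1 against replicate 2 gave 1669 and the crossed split 973. Limma with adjustment gave 0 in each. That cannot separate the splits if few genes differ, since for aluminium against control it recovered 0 changed genes in data simulated with this spread and few changed genes. The fold rule gave 4455, 5110 and 4059. With 3 splits no share under 0.05 can be had. A biological difference between the pools, such as their growth before treatment, was not tested.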

How the results depend on the processing

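Array weights, single replicate numbers and counts at an unadjusted p were added after the data had been seen. At a threshold of 0.05, limma found 0 probe sets in every setting tried, with a smallest adjusted p from 0.0954 to 1.00. At 0.1 it found 0 with the default spread and 1 with trend and robust estimation, which has no gene name in the table used here (−4.14). With the replicate number as a block, it found 0 (smallest adjusted p 0.899) and 1122 at an unadjusted p, and the correlation of deviations of same-numbered arrays was 0.0867. Leaving out an array leaves 1 in an arm, assumed to vary like the other group. The number of lists past the threshold, 1, ranged from 0 to 2 when each array was left out, and was 0 with an estimated correlation, 0 with fry and 0 with camera on ranks. The photosynthesis median ranged from −2.14 to −1.28 without each array. Its −1.91 no longer passed with an estimated correlation (adjusted p 0.927), fry (0.795) or ranks (0.0782). With 4 arrays, an estimated correlation and fry have little power and do not refute the call. The aluminium resistance median ranged from 0.60 to 1.51 and never passed. The fold count ranged from 6638 to 9816 without each array. With one array in an arm fewer comparisons can overlap. It was 11041 from the replicate 1 arrays and 7284 from the replicate 2 arrays. Without the dimmest 50% of probe sets, fewer were counted, 1967 by the fold rule and 454 at an unadjusted p. The count at an unadjusted p ranged from 616 to 2532 without each array, and the cause was not tested. Of 61 named genes, 16 reversed, each when an array was left out: CCR2 (−4.57 to 0.92), LDH1 (−2.82 to 1.08), EXPA4 (−1.95 to 0.33), MCCA (−1.83 to 0.34), ETFQO (−1.47 to 1.08), HSP17.6C (AT1G53540, −1.47 to 2.82), IAA29 (−1.39 to 1.90), EXPA7 (−1.37 to 0.46), COR15A (−1.12 to 2.32), GH3.3 (−0.97 to 0.14), PEX4 (−0.87 to 0.31), ATHSP22.0 (−0.86 to 2.71), UGT74B1 (−0.59 to 0.94), GI (−0.18 to 0.71), SCL-alpha2 (−0.11 to 3.10) and AUR1 (−0.051 to 0.32). A gene whose groups do not overlap cannot reverse when 1 array is left out, so its constant sign is no sign of stability. The genes named for the smallest p were chosen without overlap. Among the named genes whose groups overlapped, only GR1, GSTU22, PDF1.2 and PYK10 kept their sign without each array. No named gene passed in any of 809 values. Signal above background, on 35.1% to 45.3% of probe sets, limits what dim genes can show. Counts of 0 by limma are no evidence against change in a few genes, since it recovered 0 in data simulated with this spread and few changed genes. A change in a large share of the genes was not simulated.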

Other observations

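All families here, and the tests of 1 array alone and of the share of shoot tissue, were chosen after the data had been seen. The genes of the plastid genome were lower with aluminium in each of the functional classes examined here. Those of the photosystems, the cytochrome complex, ATP synthase and Rubisco had a median log2 difference of −1.41 over 33 genes, 32 of them lower (adjusted p = 9.27e-11 by camera of limma). That call was lost with an adjusted p = 0.628 with an estimated correlation and with fry (0.593). Both tests have little power with 4 arrays, so such a loss leaves a call undecided. The NAD(P)H dehydrogenase genes had −1.44 over 10 genes (adjusted p = 1.65e-04), and those of the plastid ribosome and RNA polymerase −2.00 over 19 genes (adjusted p = 9.0e-13). Both of these calls were lost in the same way, with an adjusted p = 0.628 with an estimated correlation and 0.593 with fry. Camera on ranks, at the preset correlation, kept all 3 calls (adjusted p = 7.79e-10, 1.98e-04 and 8.38e-08, in the order given). In the last class 18 genes were lower, rps19 by the most (−5.51) and also rps2 (−4.33) and rps3 (−3.61), while rps16 stood at 1.33. Over all genes 0 of them passed limma, and adjusted over the list alone 3 did. Without control replicate 1 the medians of the NAD(P)H dehydrogenase, photosystem and ribosome classes were −0.61, −0.53 and −1.41, each smaller in size than with all arrays. Of these, only the NAD(P)H dehydrogenase class no longer passed camera there. Without control replicate 2 the medians were −2.30, −2.14 and −2.66 in the same order. Genes of the mitochondrial genome had a median of −0.74 over 15 genes and did not pass (adjusted p = 0.147). It was −0.24 without control replicate 1, −0.33 without aluminium replicate 1 and −0.47 without aluminium replicate 2, but −0.88 without control replicate 2.

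Nuclear genes for photosystems, chlorophyll synthesis and the Calvin cycle outside the fixed list had a median of −0.78 over 23 genes, 17 of them lower (adjusted p = 0.0137, and adjusted p = 0.628 with an estimated correlation). SBPASE of the Calvin cycle stood at −1.12, PSAN of photosystem I at −1.36 and LHCB4.2 at −1.54. Another 6 genes were higher, by up to 1.00. The groups did not overlap in 3 of the higher and 10 of the lower genes. The median was −0.24 without aluminium replicate 1 (adjusted p = 0.850) and −0.64 without control replicate 2 (adjusted p = 0.141), both short of the threshold, and −1.20 without aluminium replicate 2. Without the dimmest 50% of probe sets it was −0.72 (adjusted p = 0.0673). The choice by symbol also took TKL and TPI, which are not plastid genes of photosynthesis. Without both, a choice made after their values were seen, the median was −0.82 over 21 genes (adjusted p = 0.00183, but adjusted p = 0.628 with an estimated correlation and 0.593 with fry) and −0.26 without aluminium replicate 1 (adjusted p = 0.460).

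Plastid-encoded genes were lower on the aluminium arrays as a whole, with a median of −1.63 over 62 genes, 60 of them lower and 44 with both aluminium arrays below both controls. Leaving out 1 array tested a single array as the whole source. The median was −1.48 and −1.49 without aluminium replicate 1 and 2, and −0.88 and −2.33 without control replicate 1 and 2. Each lay at percentile 0 of matched random lists, but those lists do not measure the spread between arrays. Gene by gene, the controls differed from each other by a median of 1.49 and the aluminium arrays by 0.028. The array medians were 9.88 and 9.56 with aluminium against 12.28 and 10.63 in controls. The split by replicate number (0.74, percentile 100) and the crossed split (−0.84, percentile 0) were as extreme against their own lists. Both contain the gap between the controls, so they are no separate measure of the spread. Part of the difference may come from control replicate 1, and the rest stays open. Poly dT primes RNA without poly(A) tails poorly, and unequal priming between arrays could shift plastid and mitochondrial transcripts, whose medians were both low (the mitochondrial one −0.74, at percentile 0.39 of matched random lists, but −0.24 without control replicate 1 and −0.33 without aluminium replicate 1), whereas 25S ribosomal RNA was brightest on aluminium replicate 1 (3511), as were the added controls. Against it, the nuclear photosynthesis genes were low too, at percentile 0.01 of such lists. That meets a bound set before this test, but for a family chosen after the data had been seen. It also rests on aluminium replicate 1, without which they lay at percentile 3.34. Without aluminium replicate 2, control replicate 1 and control replicate 2 they lay at percentiles 0, 0.02 and 0.17. In the split by replicate number and the crossed split they lay at 19.01 and 6.67. A smaller share of shoot tissue would raise root markers, whose median of −0.45 lay at percentile 24.4 over only 3 genes and decides nothing, and a biological response of the plastid to aluminium stays open as well.

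The other families by symbol did not pass, with adjusted p from 0.171 to 0.859. Medians were −0.63 for endoglucanases of family 9, −0.44 for expansins, −0.30 for serine carboxypeptidase-like proteins, −0.24 for beta-glucosidases, −0.16 for xyloglucan endotransglucosylases and −0.09 for trichome birefringence-like proteins. They were 0.58 for ATG8 proteins of autophagy, 0.28 for SWEET sugar transporters, 0.25 for UDP-glycosyltransferases, 0.21 for CYP71B cytochromes, 0.19 for ubiquitin-conjugating enzymes, 0.11 for AGAMOUS-like factors and 0.04 for glutathione transferases. Alternative NADH dehydrogenases and electron transfer flavoproteins had a median of −0.11, but a mean of 0.14 and an upward test.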
